A study of Homo sapiens with 16 samples.

How the data were processed

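Gene expression was measured by polyA RNA sequencing in MV411 and OCI-AML3 cells treated with 5 µM of the ENL inhibitor or DMSO for 24 h, per the labels' protocols. Libraries of the first MV411 batch and of OCI-AML3 were sequenced on another instrument model than those of the second batch, per the labels' protocols. The submitters' processing notes name HISAT2 2.2.1, kallisto 0.46.2, DESeq2 1.28.1 and the human genome build hg19, without saying which tool made which file. The 16 samples were grouped by title into line, treatment and batch. The letters A to D of the second batch were tested as a block only as an alternative.

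For the second batch the authors deposited TPM values for 25349 gene symbols in each of 8 files, per the file headers. Each file sums to 1000000, and 6901 symbols are at 0 in all 8. TPM keeps no depth. For the first MV411 batch and OCI-AML3 the authors deposited tables of 12516 and 12304 genes with a mean normalized count, a log2 fold change with its standard error, a test statistic or score, a p-value and an adjusted p-value. These tables also hold a normalized signal column for each library, which the authors made by dividing the gene's read count by a factor per library. When each of these columns was divided by the value of 1 read, 100.0% of its values were whole within 0.01. Each listed gene has at least 10 reads in each library of its table, so genes near 0 in any library are not listed. The 2 treated MV411 columns had equal reads in 12516 of 12516 genes (chi-square per degree of freedom 0.0, against 6.11 for the DMSO pair and 9.26 and 6.42 for the OCI-AML3 pairs) and were used as their mean, as 1 sample, in the limma fits. Results that rest on the deposited standard errors or statistic count that library as a pair. Columns of the tables carry other replicate numbers than the labels, so no column was tied to a single sample or paired. No column of the tables was left unmapped to a group.

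The design fixed before the data were examined named count tests for the second batch, to be replaced by limma if the files held TPM. It also named a count test for the tables if they held counts. As the second batch held TPM, limma 3.58.1 in R 4.3.3 was run on log2(TPM + 1), with a variance trend, over the 12192 genes that reached 1 TPM in at least 4 libraries, and p-values were Benjamini-Hochberg adjusted with a threshold of 0.05. The tables hold normalized signal, so no count test was run on them and their main results are the authors' deposited adjusted p under 0.05, although reads could be worked back from the columns. For the difference between batches the limma estimate took the place of a planned count-based one. An adjusted p that is missing in a table stayed missing. The difference between lines was the difference of the deposited log2 fold changes over the root of the sum of their squared standard errors. The difference between MV411 batches was computed in the same way with the limma estimate of the second batch. Changes relative to the median gene subtract the table's median log2 fold change and use the deposited standard errors. As a fit that counts the repeated library once, limma was run on log2 of the 7 distinct libraries of both tables after median-of-ratios scaling within each table, with 1 added to the values. It assumes that the single treated MV411 library varies like the other libraries. This fit, the changes relative to the median gene and the use of the estimated correlation to call lists were chosen after the data were examined.

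Gene lists (29) were written before the data were examined, and those with at least 5 tested members were used. They were tested with limma's camera (preset correlation 0.01, and an estimated correlation beside it) in the second batch and with cameraPR on the authors' statistic in the tables, adjusted over the lists. HOXA and HOXB cluster genes had enough members in OCI-AML3 only, and epithelial and fibroblast markers in no comparison. Mitochondrially encoded genes are listed only in the tables. Symbols were matched to current ones through synonyms of the RefSeq annotation of GRCh38.p14, used for names only: 24096 of 25349, 12032 of 12516 and 11841 of 12304 matched. No coordinates are given because the files use another build. CXCL8 is listed as IL8 in the tables.

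The genes named were chosen by a rule set in advance: 12 genes tied to ENL, KMT2A fusions and myeloid maturation, the 10 largest rises and falls per comparison among called protein-coding genes with a mean of at least 5 TPM and full separation of the groups (tables: a mean normalized count of at least 100), up to 4 members per list with the smallest p, and the 5 smallest adjusted p in each direction for the differences between lines and between batches. The limit to protein-coding genes and the removal of Y-linked genes and of open reading frame names were added to the rule after the data were examined. Some genes that met the rule are not reported here.

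The fits were tested on simulated data with 200 changed genes, or 179 for the difference between the batches. Recovery depends on the share of genes that change, which is unknown in the data. Noise was drawn with each gene's residual SD as estimated from these few libraries, so recovery in the data can differ. With 4 libraries against 4, 79.4% of genes changed by 0.5 on the log2 scale and 94.6% of those changed by 1 were recovered, with 9 false calls of 182. For OCI-AML3, limma on 2 against 2 libraries recovered 0% and 20.4%, and for MV411 on 2 against 1 it recovered 0% at both sizes. The test of the difference between the tables recovered 61.0% of differences of 1, with 4 false calls of 126. The 7-library fit recovered 11.8% and 51.4% of changes of 0.5 and 1 in MV411, 19.5% and 64.4% in OCI-AML3, and 0% and 16.8% of differences between the lines, with 0, 3 and 0 false calls. The difference between the batches with that fit recovered 4.9% and 44.3%, with 0 false calls. Alternatives covered scaling, filters, pseudocounts, thresholds, the list tests, the replicate block and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.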

Results

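RNA sequencing of polyA RNA was used to ask which genes change in acute myeloid leukaemia cells when the acyl-lysine reader ENL is inhibited. ENL is a YEATS-domain chromatin protein encoded by MLLT1, and the inhibitor carries the code name TDI-055 in titles of the first MV411 batch and OCI-AML3 and TDI-11055 in those of the second MV411 batch. The treatment protocol of all samples names TDI-055, and both are called the compound here. Both lines came from acute myeloid leukaemia: MV411 (also written MV4;11), which carries a KMT2A-AFF1 fusion and an internal tandem duplication of FLT3, and OCI-AML3, which carries an NPM1 mutation. Cells received 5 µM of the compound or its solvent DMSO for 24 h. The 16 samples formed 6 groups: a first MV411 batch with 2 DMSO and 2 treated samples, an OCI-AML3 set with 2 and 2, and a second MV411 batch with 4 and 4. The second batch came as TPM values, which keep no sequencing depth, so its depth is unknown. Between 11998 and 12213 genes reached 1 TPM in each of its libraries. The first MV411 batch and OCI-AML3 came as tables of the authors' own comparisons with normalized counts per library, which correspond to 12424322 to 17636201 reads in the listed genes. No label says that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

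The compound raised monocyte, MHC class II and lysosome genes and lowered MYC-driven nucleolar, heat shock, and ATF4 and stress response genes in the second MV411 batch. On the log2(TPM + 1) scale LSP1, an actin-binding protein of leukocytes, showed the largest rise among the named genes. It rose from 5.07 ± 0.42 to 36.9 ± 0.96 TPM (SD, n = 4 each). IGLL1, a surrogate light chain of immature B cells, fell most among the named genes, from 58.4 ± 7.4 to 18.7 ± 2.8 TPM. In all, 2437 genes were higher and 2716 lower among 12192 tested (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05). Most changes were small: 124 genes rose and 16 fell by 2-fold or more. All 4 treated libraries lay on one side of all 4 DMSO libraries for 39.7% of the tested genes, where chance gives 2.86%. Fold changes on this scale understate the change of genes near 1 TPM.

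Besides LSP1, the 10 largest rises by the naming rule were in the chemokines CXCL8 (log2 fold change 2.49, SE 0.14) and CCL3 (2.40, SE 0.25), the small GTPase RHOB (2.33, SE 0.25), the transcription factors KLF2 (2.18, SE 0.30), JUN (1.82, SE 0.28) and EGR1 (1.79, SE 0.090), the neutrophil adaptor PRAM1 (1.88, SE 0.11), the G-protein regulator RGS1 (1.86, SE 0.20) and annexin A1, ANXA1 (1.66, SE 0.067). After IGLL1, the largest falls included the interleukin 7 receptor IL7R (−1.26, SE 0.066), GCH1, the first enzyme of tetrahydrobiopterin synthesis (−1.22, SE 0.11), the activin subunit INHBA (−1.15, SE 0.093), the granule protease cathepsin G, CTSG (−1.15, SE 0.033), TMEM52 (−1.11, SE 0.15), the alanine transaminase GPT2 (−1.07, SE 0.033), the Nogo receptor RTN4R (−0.98, SE 0.045) and the neuropeptide galanin, GAL (−0.96, SE 0.056). KLF2, JUN and RHOB also varied among the DMSO libraries: JUN had 64.0 ± 32.2 TPM there and 213 ± 43.6 TPM in treated libraries.

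**Figure D1:**
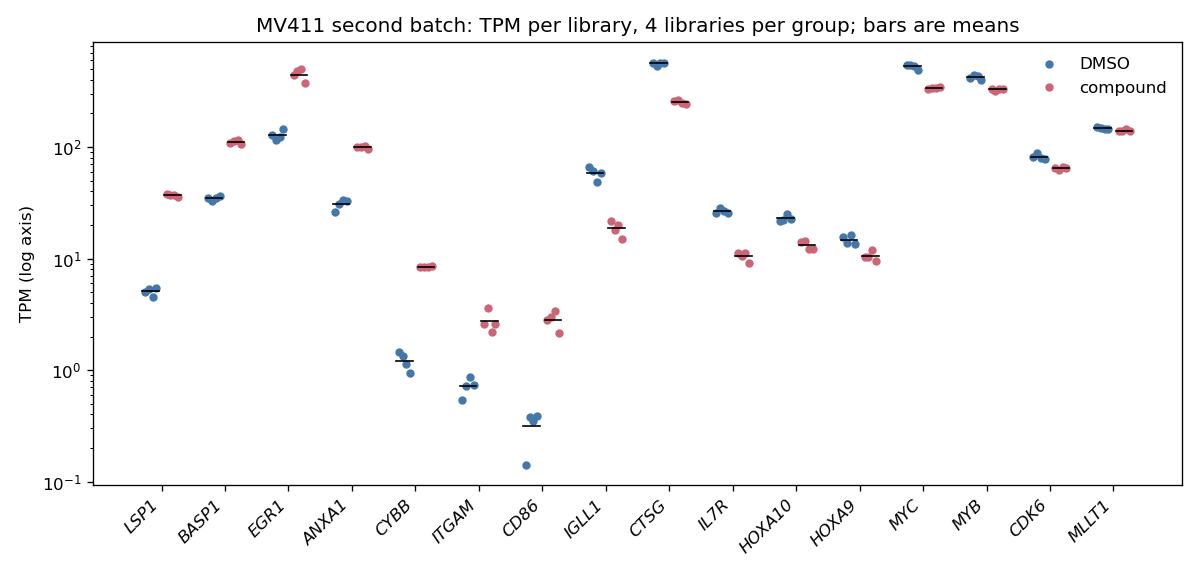
TPM per library (log axis) of 16 named genes in the second MV411 batch, 4 DMSO and 4 treated libraries, with bars at the group means. LSP1 lies at 36.9 TPM in treated against 5.07 TPM in DMSO libraries and CTSG at 254 against 563 TPM, while MLLT1 lies at 140 against 148 TPM.

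Of the 33 tested monocyte and macrophage genes, 29 rose and none fell (29 adjusted over the list alone), and the list stood above other genes by camera (adjusted p = 0.00173 with an estimated correlation). With a preset correlation 14 of 25 lists passed camera, but up to 6 also passed in splits of the libraries balanced for treatment. Lists are therefore called here with an estimated correlation, which left 8 and passed none in those splits. In those splits the treatment difference enters the spread from which that correlation is estimated. Passing none there is therefore no measure of its error. ITGB2, the integrin chain CD18, rose from 144 ± 2.5 to 251 ± 6.7 TPM, the M-CSF receptor CSF1R from 31.1 ± 0.85 to 60.4 ± 0.64 TPM, and the receptor adaptor TYROBP from 354 ± 13.5 to 612 ± 24.5 TPM (SD, n = 4). The surface markers ITGAM (CD11b) and CD86 rose from low levels, 0.72 ± 0.14 to 2.74 ± 0.59 TPM and 0.32 ± 0.12 to 2.84 ± 0.53 TPM. CD14 reached 1 TPM in 1 library and was not tested. All 6 tested MHC class II genes rose (6 adjusted over the list alone, adjusted p = 0.012 with an estimated correlation), among them the invariant chain CD74 from 433 ± 7.7 to 926 ± 33 TPM and the master regulator CIITA from 4.28 ± 0.30 to 10.2 ± 0.73 TPM. HLA genes share sequence, so values such as that of HLA-DRB1 (log2 fold change 1.34, SE 0.091) can include reads of related genes.

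Lysosome genes rose in 25 of 34 tested members and fell in 2 (27 and 3 adjusted over the list alone, adjusted p = 0.00221 with an estimated correlation). Saposin precursor PSAP rose from 105 ± 4.5 to 190 ± 3.3 TPM and cathepsin B, CTSB, from 73.4 ± 2.7 to 115 ± 2.4 TPM. Interferon response genes rose in 16 of 29 and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.024 with an estimated correlation), with STAT2 at a log2 fold change of 0.70 (SE 0.048) and IFI6 at 1.35 (SE 0.13). In the NF-kB and cytokine list 9 of 17 rose and 2 fell (9 and 2 adjusted over the list alone), including CCL2 (1.45, SE 0.054) and IL1B (1.21, SE 0.087). The list test was not passed with an estimated correlation (adjusted p = 0.0708). Immediate early genes, which respond within minutes to growth factors, serum or handling, rose in 16 of 21 (17 adjusted over the list alone) and none fell. Their list did not pass with an estimated correlation (adjusted p = 0.181).

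MYC itself fell from 527 ± 26 to 339 ± 6.4 TPM, and 44 of 46 MYC-driven nucleolar genes fell with none higher (44 adjusted over the list alone, adjusted p = 0.00221 with an estimated correlation). Nucleolin, NCL, fell from 2054 ± 31 to 1612 ± 10 TPM, nucleophosmin, NPM1, from 1743 ± 11 to 1372 ± 14 TPM, and the RNA helicase DDX21 from 257 ± 6.4 to 185 ± 2.4 TPM. Heat shock genes fell in 14 of 16 and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 0.012 with an estimated correlation), with HSPA8 at 2804 ± 43 and 1879 ± 44 TPM. ATF4 and stress response genes fell in 17 of 28 and rose in 5 (17 and 5 adjusted over the list alone, adjusted p = 0.012 with an estimated correlation), led by the serine synthesis enzyme PSAT1 (−0.87, SE 0.026) and the amino acid transporter SLC7A5 (−0.47, SE 0.019). S phase genes fell in 24 of 39 and rose in 1 (25 and 1 adjusted over the list alone, adjusted p = 0.0201 with an estimated correlation), as for the replication licensing factor CDC6 (−0.39, SE 0.031). Mitosis genes fell in 19 of 38 and rose in 1 (20 and 1 adjusted over the list alone). Their list did not pass with an estimated correlation (adjusted p = 0.315).

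Among the known targets of KMT2A fusions, HOXA10 fell from 23.0 ± 1.5 to 13.2 ± 1.1 TPM and HOXA9 from 14.8 ± 1.3 to 10.6 ± 1.1 TPM (SD, n = 4). Smaller falls were seen in MYB (−0.36, SE 0.034), CDK6 (−0.34, SE 0.043), SOX4 (−0.51, SE 0.034) and MEIS1 (−0.21, SE 0.045). The cyclin CCNA1 rose (0.76, SE 0.057). Of the 30 tested genes in the leukaemia stem and KMT2A-fusion target list, 15 fell and 5 rose (15 and 5 adjusted over the list alone), and the list did not pass with an estimated correlation (adjusted p = 0.675). FLT3 had a log2 fold change of −0.09 (SE 0.027) and MLLT1, which encodes the target, one of −0.07 (SE 0.025), and both calls were lost in several alternative fits. BCL2 gave 0.03 (SE 0.042, adjusted p = 0.566). The granule list went both ways: 6 of 15 genes rose and 4 fell (6 and 4 adjusted over the list alone), with CTSG and MS4A3 (−0.38, SE 0.018) lower and azurocidin, AZU1 (0.38, SE 0.021), higher.

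Cytosolic ribosomal protein genes were higher in 29 of 49 and lower in 4 (30 and 4 adjusted over the list alone), and the list did not pass with an estimated correlation (adjusted p = 0.286). Replication-dependent histone genes were higher in 8 of 25 (8 adjusted over the list alone, adjusted p = 0.259 with an estimated correlation), although polyA selection leaves most of their transcripts out. MHC class I genes were higher in 8 of 11 and lower in 3 (8 and 3 adjusted over the list alone), where B2M (0.58, SE 0.021) rose and the chaperone CALR (−0.39, SE 0.015) fell, and the list did not pass (adjusted p = 0.164 with an estimated correlation). Glycolysis, cholesterol synthesis, p53 target, respiratory chain, BCL2 family, progenitor, and elongation and acyl-lysine reader complex genes did not pass as lists, with adjusted p from 0.263 to 0.999 with an estimated correlation. Erythroid and megakaryocyte markers (6 tested, adjusted p = 0.726) and lymphoid markers (5 tested, adjusted p = 0.868) did not pass either. Median and mean differed in sign in the erythroid, lymphoid, progenitor and glycolysis lists.

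**Figure D2:**
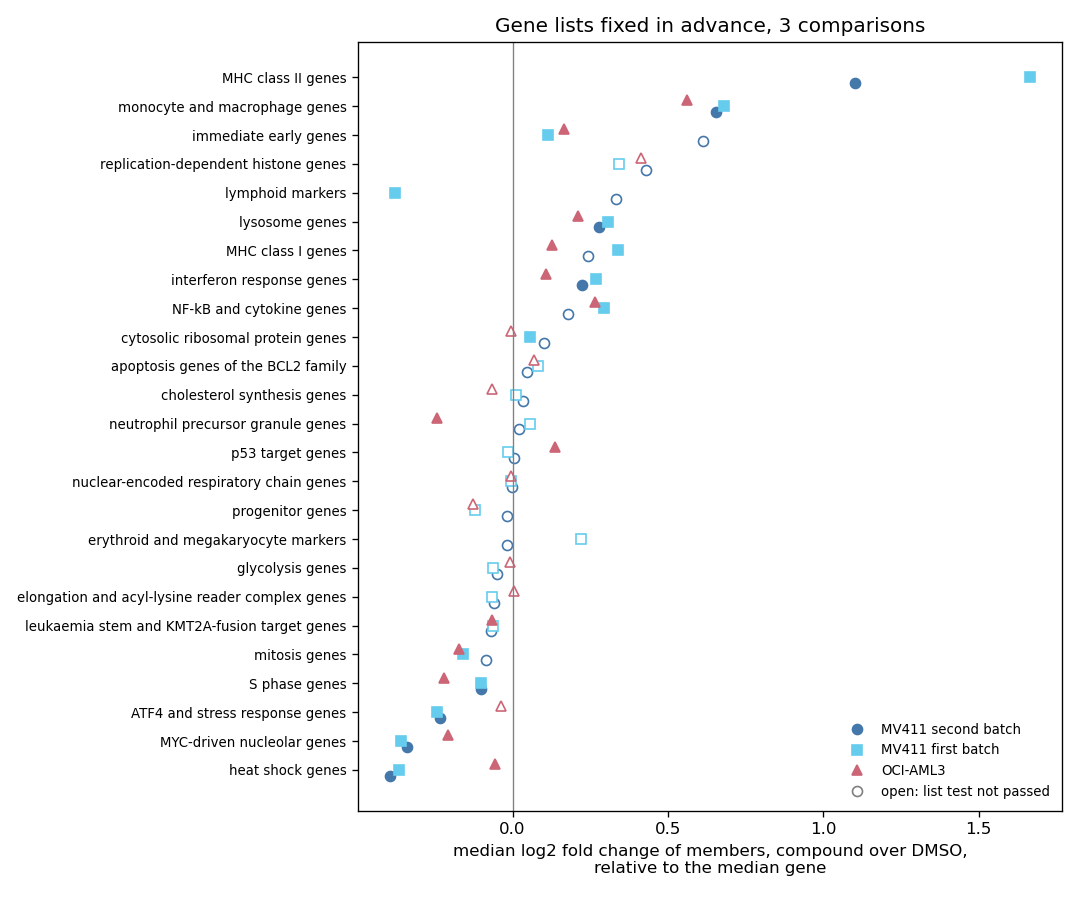
Median log2 fold change of each gene list, compound over DMSO and relative to the median gene, in the second MV411 batch (circles), the first MV411 batch (squares) and OCI-AML3 (triangles). Filled symbols passed the list test. For the second batch it used an estimated correlation, and for the others a preset correlation and the statistic taken relative to the median gene. Filled and open symbols are therefore not comparable between the second batch and the others. Monocyte and macrophage genes lie above 0 and MYC-driven nucleolar genes below 0 in all 3 comparisons.

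In the first MV411 batch monocyte and MHC class II genes were again among those that rose, and MYC-driven nucleolar and heat shock genes among those that fell. LSP1, the NADPH oxidase subunit CYBB, PRAM1, HLA-DRB1 and BASP1 had the largest rises, and IGLL1, GPT2, CTSG and IL7R were among the largest falls. The authors' deposited table called 402 genes higher and 4139 lower of 12516 (their adjusted p under 0.05). Its median gene lay at a log2 fold change of −0.24, so that 77.2% of genes were below 0. Relative to that median 1072 genes were higher and 996 lower, by a Wald test with the deposited standard errors. The 2 treated columns held 1 library: their values had the constant ratio 0.9585 in 12516 of 12516 genes, and they differed by less than the sampling noise. The deposited fold changes equal those of the column means within 0.000842 on the log2 scale, so the authors' fit used that library as a pair. All first-batch values here that rest on the deposited standard errors or statistic count it as a pair too, and only limma fits count it once. With it counted once, limma over the 7 distinct libraries of both tables (median-of-ratios size factors) gave 410 genes higher and 333 lower of 11556. That total of 743 was 218 without the first and 221 without the second MV411 DMSO library. The 7-library fit also changes the scaling and the test, so its smaller number of calls is not due to the repeated library alone. Changes in both tables are given below relative to the median gene.

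Relative to the median gene in the authors' deposited table, LSP1 rose by a log2 fold change of 2.97 (SE 0.17), CYBB by 2.91 (SE 0.21), PRAM1 by 2.11 (SE 0.32), HLA-DRB1 by 2.07 (SE 0.18), the membrane protein BASP1 by 2.05 (SE 0.13), HLA-DRA by 2.03 (SE 0.37), the sugar-phosphate transporter SLC37A2 by 1.77 (SE 0.28), CD84 by 1.76 (SE 0.26), PAQR8 by 1.74 (SE 0.24) and SEMA6B by 1.73 (SE 0.14). In the same table IGLL1 changed by −1.85 (SE 0.26), GPT2 by −1.31 (SE 0.10), CTSG by −1.26 (SE 0.082), IL7R by −1.24 (SE 0.15), INHBA by −1.23 (SE 0.17), MAMDC4 by −1.22 (SE 0.24), GCH1 by −1.08 (SE 0.28), MFSD9 by −1.08 (SE 0.34) and ATG10 by −1.08 (SE 0.29). In the 7-library fit, which counts the treated library once, all 8 of the 10 largest rises that it lists passed, and 4 of 7 of the largest falls did. HOXA9 fell by 0.76 (SE 0.12), HOXA10 by 0.65 (SE 0.13), MYC by 0.69 (SE 0.071), MYB by 0.34 (SE 0.056) and CDK6 by 0.24 (SE 0.062). MEIS1 (0.02, SE 0.11), FLT3 (−0.12, SE 0.060), BCL2 (−0.04, SE 0.082) and MLLT1 (−0.07, SE 0.10) did not pass relative to the median gene.

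By list in the first MV411 batch, monocyte and macrophage genes rose in 25 of 32 relative to the median gene with none lower (the authors' own calls were 15 higher, and 16 adjusted over the list alone). MHC class II genes rose in 7 of 9 (7 by the authors' calls) and lysosome genes in 16 of 35, with none lower in either on this scale, while the authors called 8 lysosome genes higher and 4 lower. Too few MHC class II genes were in the 7-library fit to be counted there. MYC-driven nucleolar genes fell in 37 of 46 and rose in 1, heat shock genes fell in 12 of 19 and rose in 1, and ATF4 and stress response genes fell in 13 of 28 and rose in 1, where the authors called 45, 15 and 16 lower and none higher. Mitosis genes fell in 9 of 38 and rose in 1, and S phase genes fell in 6 of 38, where the authors called 31 and 28 lower. These calls count the repeated library as a pair. With it counted once, in the 7-library fit, 13 of 29 monocyte and 10 of 35 lysosome genes rose, and 24 of 46 nucleolar, 11 of 18 heat shock, 12 of 28 ATF4, 1 of 38 mitosis and 1 of 38 S phase genes fell, with none called the other way. By cameraPR on the authors' statistic 19 of 26 lists passed, with adjusted p = 1.71e-17 for monocyte, 6.34e-17 for MHC class II, 5.04e-06 for lysosome, 9.9e-31 for nucleolar, 7.8e-24 for heat shock, 3e-07 for ATF4, 3.43e-07 for mitosis and 3.96e-06 for S phase genes. These 8 lists also passed on the statistic relative to the median gene, as did MHC class I, interferon response, NF-kB, immediate early and mitochondrially encoded genes. Lymphoid markers passed, as lower, on that statistic only (adjusted p = 0.0078). The leukaemia stem and KMT2A-fusion target list passed, as lower, by cameraPR on the authors' statistic (adjusted p = 0.000193). Relative to the median gene it did not pass (adjusted p = 0.0805). Of its 32 tested genes 10 fell and 5 rose on that scale, where the authors called 19 lower and 2 higher. By cameraPR on ranks immediate early genes did not pass (adjusted p = 0.118), nor did MHC class I genes with a correlation of 0.05 (adjusted p = 0.0687). These p-values use a preset correlation, with which up to 6 lists passed in balanced splits of the second batch. Examples are the monocyte genes CD36 (0.88, SE 0.097) and CD68 (0.83, SE 0.093), PSAP (0.99, SE 0.075), NCL (−0.42, SE 0.050), HSPA8 (−0.64, SE 0.057) and PSAT1 (−0.91, SE 0.086). Immediate early genes rose in 5 of 21 relative to the median gene with none lower, including EGR1 (1.19, SE 0.078). The authors called 5 of them higher and 4 lower. Cytosolic ribosomal protein genes showed how much the offset matters: 42 of 49 were called lower by the authors, while relative to the median gene 3 were higher and none lower.

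The second batch, with its own DMSO libraries, tests the first-batch calls. Of 373 genes that the authors' table called higher and that were tested in both, 340 were higher in the second batch, where independent lists would share 78.4. Of 3958 called lower, 2126 were lower there, where independent lists would share 958.3. Calls in the opposite direction in the second batch numbered 1 for the higher genes and 144 for the lower ones. Taken relative to the median gene, 837 of 1013 higher genes and 804 of 952 lower genes were called in the same direction, where independent lists would share 212.9 and 230.5. Fold changes had a Pearson r of 0.72 across 10862 genes, which are not independent replicates. The name of the compound in the titles and the sequencing instrument also differed between the batches. So did the scale, with normalized counts in the first batch and log2(TPM + 1) in the second. A test of the difference between the batches called 2793 genes, of which 2770 were lower in the first batch. After subtraction of each median 104 differed, and with the treated library counted once none did (limma, 556 of 10319 at an unadjusted p under 0.05, where chance gives 516). On simulated data that last test found 44.3% of differences of 1 on the log2 scale and 4.9% of those of 0.5. Differences of 0.5 were thus rarely found in the simulation, and recovery in the data can differ.

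**Figure D3:**
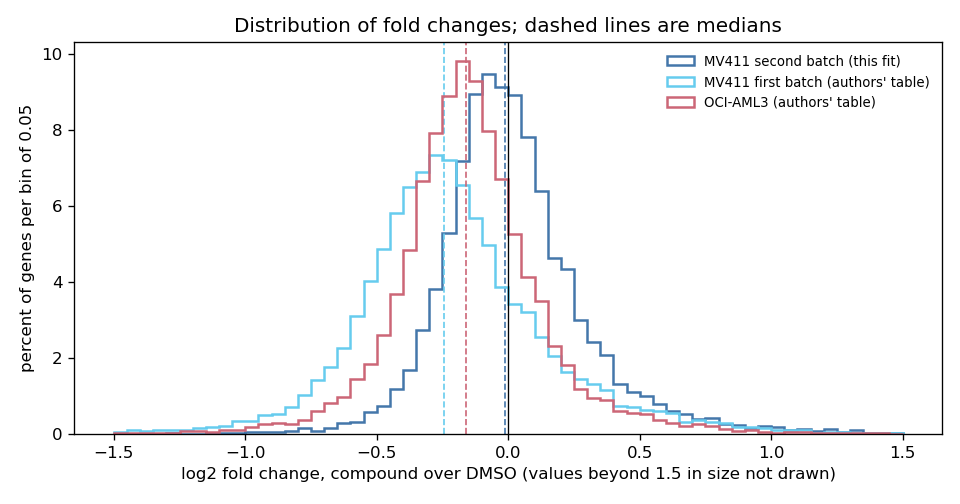
Distribution of log2 fold changes, compound over DMSO, as the percent of genes per bin of 0.05 in each comparison, with dashed lines at the medians. The medians lie at −0.01 in the second MV411 batch, −0.24 in the first MV411 batch and −0.16 in OCI-AML3.

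In OCI-AML3 monocyte genes rose, and granule genes such as MS4A3 fell together with MYC. Of the genes picked for the largest called rises LSP1 was again first, followed by S100A9, IPCEF1, EPB41L3, ANXA1 and S100A8, and HUNK, MBOAT2, USP31, THBS4 and SLC4A11 fell most. The authors' deposited table called 114 genes higher and 778 lower of 12304, with no adjusted p for 3101 genes. Its median gene lay at −0.16 and 76.1% of genes were below 0. With the median subtracted 230 were higher and 88 lower, so that most lower calls were lost and none turned to a higher call. The 7-library fit called 278 higher and 163 lower, and between 110 and 272 in all when any 1 of 6 libraries was left out. The labels give 5 µM for the treated samples while the names of their columns say 1 µM, and the dose of this comparison is therefore uncertain.

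Relative to the median gene in the authors' deposited OCI-AML3 table, LSP1 rose by 1.79 (SE 0.23), the calprotectin subunits S100A9 by 1.61 (SE 0.15) and S100A8 by 1.22 (SE 0.16), IPCEF1 by 1.45 (SE 0.28), the membrane skeleton protein EPB41L3 by 1.44 (SE 0.15), ANXA1 by 1.25 (SE 0.12), the polyamine enzyme SAT1 by 1.11 (SE 0.25), ZDHHC2 by 1.10 (SE 0.22), the receptor CD244 by 1.07 (SE 0.26) and the chromatin remodeller INO80 by 1.05 (SE 0.16). The kinase gene HUNK fell by 1.21 (SE 0.24), MBOAT2 by 1.09 (SE 0.28), USP31 by 1.09 (SE 0.25), THBS4 by 0.94 (SE 0.20), the transporter SLC4A11 by 0.92 (SE 0.22), ANKRD18B by 0.89 (SE 0.22), PTBP2 by 0.80 (SE 0.20) and RAD54L by 0.80 (SE 0.20). TTC28 (−0.83, SE 0.30) and OSBPL3 (−0.78, SE 0.28), which the authors called lower, did not pass relative to the median gene. MYC fell by 0.62 (SE 0.11) and HOXA10 by 0.34 (SE 0.10). HOXA9 (0.00, SE 0.12), MYB (−0.24, SE 0.096), CDK6 (−0.11, SE 0.084), FLT3 (0.06, SE 0.14) and MLLT1 (−0.03, SE 0.20) did not pass. CD86 had a deposited log2 fold change of 2.84 (SE 0.33) but no adjusted p in the table.

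By list in OCI-AML3, monocyte and macrophage genes rose in 13 of 33 relative to the median gene with none lower (the authors' own calls were 10 higher, and 13 adjusted over the list alone), including FCER1G (0.81, SE 0.12). Lysosome genes rose in 4 of 36, among them cathepsin D, CTSD (0.53, SE 0.087), and immediate early genes in 5 of 22, among them EGR1 (0.71, SE 0.088). Granule genes fell in 4 of 11, among them MS4A3 (−0.54, SE 0.088) and serglycin, SRGN (−0.43, SE 0.085). S phase genes fell in 3 of 38, among them DTL (−0.72, SE 0.14) and RRM2 (−0.43, SE 0.11), MYC-driven nucleolar genes in 2 of 46, among them NOP56 (−0.37, SE 0.099), heat shock genes in 3 of 18 and HOXA cluster genes in 2 of 6, HOXA10 and HOXA13 (−0.42, SE 0.11). The authors called 6 granule, 25 S phase, 26 nucleolar, 8 heat shock and 3 HOXA genes lower, and 2 lysosome and 3 immediate early genes higher. They also called 1 immediate early gene lower. In the 7-library fit 14 of 29 monocyte and 4 of 35 lysosome genes rose, and 6 of 10 granule, 7 of 38 S phase, 7 of 46 nucleolar and 5 of 18 heat shock genes fell. By cameraPR on the authors' statistic 16 of 25 lists passed, with adjusted p = 9.36e-28 for monocyte, 2.68e-05 for lysosome, 8.64e-05 for immediate early, 6.27e-10 for granule, 3.28e-20 for S phase, 5.69e-18 for nucleolar, 6.09e-07 for heat shock and 0.000966 for HOXA genes, all with a preset correlation. Mitosis (6.15e-07) and KMT2A-fusion target genes (7.36e-05) passed as lower, and p53 target (0.00148), interferon response (0.00144) and NF-kB genes (0.000198) as higher. All of these lists also passed relative to the median gene. Relative to the median gene 1 of 38 mitosis genes fell and 2 of 28 p53 target genes rose. Of 32 KMT2A-fusion target genes 7 fell and 1 rose on that scale, where the authors called 10 lower. In the 7-library fit 9 of 31 KMT2A-fusion target genes fell and 4 rose in OCI-AML3. Of the 33 interferon response genes 0 were called on the authors' scale or relative to the median gene. The KMT2A-fusion target list did not pass by cameraPR on ranks (adjusted p = 0.0787). ATF4 and stress response genes (28 tested, adjusted p = 0.0704) and HOXB cluster genes (9 tested, adjusted p = 0.568) did not pass. MHC class II genes had too few members listed in OCI-AML3 to be tested as a list.

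Responses of the lines were compared by testing the difference of their fold changes, which can include a difference in dose if OCI-AML3 received 1 µM. The fold change was higher in MV411 than in OCI-AML3 for BASP1, CYBB, TDRD7, ABCA7 and CD74. It was higher in OCI-AML3 for ITGAL, S100A9, ZYX and INO80, while CTSG fell further in MV411. Relative to the median genes the differences, MV411 first batch minus OCI-AML3, were 1.73 for BASP1, 2.41 for CYBB, 1.22 for TDRD7, 1.09 for ABCA7 and 0.98 for CD74, and −1.22 for ITGAL, −0.88 for CTSG, −1.48 for INO80, −1.42 for S100A9 and −0.70 for ZYX. The test on the deposited values called 203 of 11556 genes, 54 with a higher and 149 with a lower response in MV411, and 130 relative to the median genes (70 and 60). With the repeated library counted once, 11 genes differed by limma over the 7 distinct libraries (1327 at an unadjusted p under 0.05), and 4 or 5 when any 1 OCI-AML3 library was left out. On simulated data this fit found 16.8% of differences of 1 on the log2 scale and 0% of those of 0.5. Its count may therefore be a low one, though recovery in the data can differ from that in the simulation. Of the 10 genes named here 6 were among them, and all 10 differed in the same direction, relative to the median genes, when the second MV411 batch took the place of the first, a comparison that shares the OCI-AML3 libraries and is not independent. HOXA9 differed by −0.76 in the fit of the 7 libraries without passing (adjusted p = 0.0666).

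Of 357 genes the authors called higher in the first MV411 batch, 52 were also called higher in OCI-AML3, where independent lists would share 3.4, and of 4065 called lower 623 were shared, against 269.1. With both medians subtracted, 140 of 1007 higher and 42 of 967 lower genes were shared, against 19.8 and 7.0. The lines were handled as separate comparisons with no shared control libraries. Across 11556 genes Pearson's r of the fold changes was 0.34, with genes not independent replicates.

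**Figure D4:**
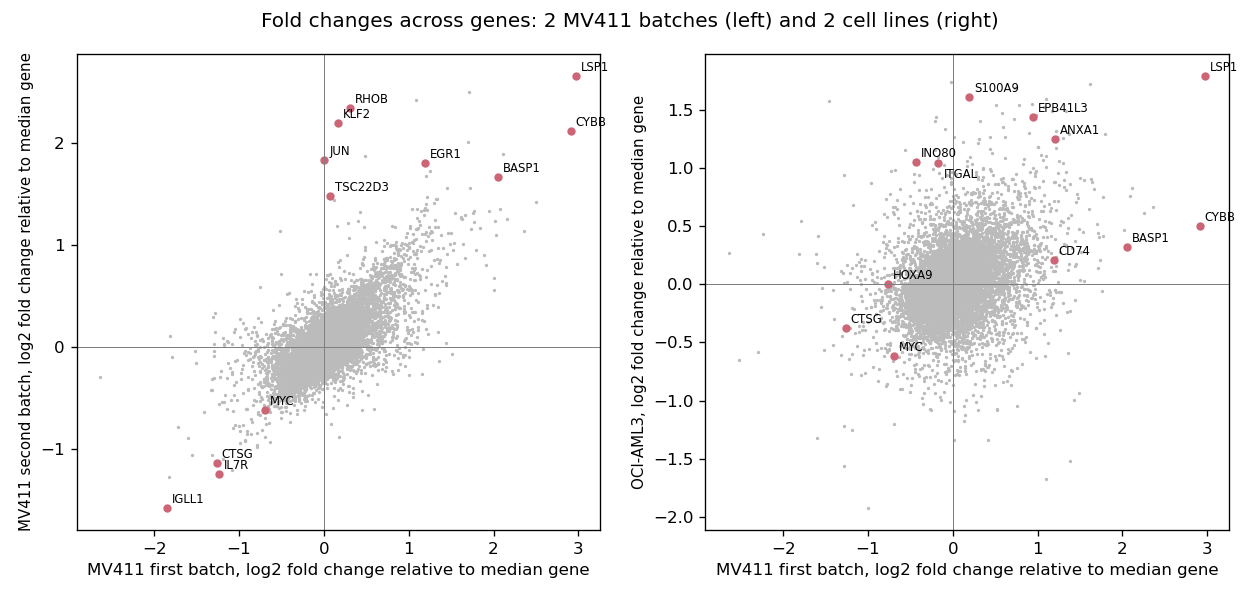
Log2 fold changes relative to the median gene, 1 point per gene, with named genes in red. The left panel sets the second MV411 batch (vertical) against the first (horizontal), and the right panel sets OCI-AML3 against the first MV411 batch. CYBB and BASP1 lie far to the right and near 0.50 and 0.32 on the OCI-AML3 axis, while S100A9 lies at 1.61 there and 0.19 in MV411.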

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

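All tests in this part were chosen after the result they bear on was seen, except the splits for gene lists with an estimated correlation. For genes of the second batch, 1 of 35 splits of the 8 libraries into 4 and 4, the real one, gave as many calls, with 5153 against at most 3 in the others. That is the smallest share this test can give, and it argues against a chance assignment of these 8 libraries. The other splits mix treatments, which raises the spread within their groups and lowers their calls. A difference between cultures would give the same result if the samples of a group were technical. For gene lists the answer depends on the correlation. With an estimated correlation 1 of 35 splits, the real one, gave as many lists, with 8 against at most 0, but these splits also guided the choice of that correlation and are no independent ground for it. The other splits also put treatment difference into the spread that sets the correlation, which makes a list less likely to pass in them. With the preset correlation, the planned main test, 6 of 35 splits gave as many lists, with 14 in the real split and 19 in the highest other. The other 5 of these put 3 libraries of one treatment with 1 of the other and keep part of the treatment difference, so they are no measure of chance. Of the 18 splits balanced for treatment none gave as many, with 6 lists in the highest, but 12 of them passed at least 1 list.

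The first pattern is the excess of falls in the authors' tables, 4139 lower against 402 higher in MV411 and 778 against 114 in OCI-AML3. Size factors computed from the reads of the listed genes are argued against, since 2 columns with equal reads have values in the ratio 0.9585. Depth is argued against in OCI-AML3, where reads in the listed genes differed between treated and DMSO libraries by −0.0209 on the log2 scale while the median gene lay at −0.1608, but in MV411 the reads differed by −0.2429 and the median gene lay at −0.2427, so depth left uncorrected by factors near 1 may account for that shift. A lower RNA content of treated cells, carried by factors from outside these genes, may give the same shift, but no value on a scale of RNA per cell was analysed here, so for OCI-AML3 it cannot be told apart from a scaling offset. Relative to the median gene the splits were 1072 higher and 996 lower in MV411 and 230 and 88 in OCI-AML3.

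The second pattern is the difference in response between the MV411 batches. It was picked out because the test of the difference called 2793 genes, 2770 of them lower in the first batch. If the offset of the authors' scaling were the source, few should remain relative to the median genes, and 104 did. A shift shared by most genes may thus account for most of the count. Subtracting a median removes such a shift whatever its origin, so this cannot tell the authors' scaling from a lower RNA content. TPM values sum to a fixed total, so the second batch could not show a fall of all genes together. With the repeated library counted once none passed by limma (556 of 10319 at an unadjusted p under 0.05, where chance gives 516), in a test that found 44.3% of simulated differences of 1. The scale differed too: first-batch estimates rest on normalized counts and second-batch ones on log2(TPM + 1), which understates the change of genes near 1 TPM. The sequencing instrument and the name of the compound in the titles also differed between the batches. None of these was tested as a source.

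Among genes compared between the MV411 batches, those with the smallest adjusted p had differences, first minus second batch and relative to the median genes, of 1.57 for JMY, 1.40 for RNF157, 0.87 for TNRC6A, 0.86 for DCAF17 and 0.69 for ACACA, and of −0.81 for ATRX, −0.66 for ZFP36, −0.37 for JUND, −0.27 for HSPA9 and −1.41 for TSC22D3. None of these 10 passed limma with the library counted once (lowest adjusted p = 0.259).

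The third pattern is the rise of immediate early genes in the second batch, where the 16 members called higher had a median log2 fold change of 0.77, against 0.14 in the first batch (quartiles 0.07 and 0.82) and 0.11 in OCI-AML3. The 16 members were chosen by their second-batch calls, which favours larger values there in any comparison of these members. Over all tested members, 21 in each batch, the median was 0.60 in the second batch and 0.11 in the first relative to the median gene. A response of like size in both MV411 batches was weighed by the ratio of the medians of the 16, 0.184, which together with their first-batch quartiles leaves it open. Another test was tried on this question and dropped again: with the repeated library counted once, 0 of 15 members differed between the batches by limma, but 11 of 15 did at an unadjusted p under 0.05, and with the deposited standard errors 9 of 16 differed, all 9 smaller in the first batch. Handling at harvest that varied from library to library would need a spread among DMSO libraries as large as the difference between the groups, and the spread of the list mean was 0.361 of it, from 4.57 to 4.81 in DMSO and from 5.14 to 5.47 with the compound, which falls short of the whole rise and leaves a part open. A handling difference shared by all treated libraries cannot be told apart from the compound, as it would follow the groups.

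The difference between the lines was picked out because a test of the difference itself called 203 genes, and 130 relative to the median genes, and line and dose are confounded if OCI-AML3 received 1 µM. Relative differences, MV411 first batch minus OCI-AML3, were 1.73 for BASP1, 2.41 for CYBB, 1.22 for TDRD7, 1.09 for ABCA7, 0.98 for CD74, −1.22 for ITGAL, −0.88 for CTSG, −1.48 for INO80, −1.42 for S100A9 and −0.70 for ZYX.

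Single libraries of the second batch stood apart from the other 3 of their group in 5 of 68 groups tested, and chance flags about 1 in 20. KLF2 had 41.0 TPM in DMSO replicate D against 13.9 to 17.5 TPM in the others. CD86 had 0.140 TPM in DMSO replicate A against 0.353 to 0.388 TPM, CTSG had 537 TPM in DMSO replicate B against 571 to 572 TPM, and MYB had 317 TPM in treated replicate B against 331 to 333 TPM. The share of TPM in the 10 highest genes was 7.20% in DMSO replicate A against 6.95% to 6.97%.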

How the results depend on the processing

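Values relative to the median gene, limma fits of the tables, quantile scaling and the fit without a variance trend were added after the data were seen. In the second batch 140 genes were called at a fold change of at least 2, and the other alternatives gave 4619 to 5362 genes, 4641 of them with the replicate block. An estimated correlation passed 8 lists, the preset one 14 and fry 21. In fry the direction of the granule list turned to lower (adjusted p = 0.00428). Of the alternative values for named genes in this batch 479 kept their call and direction and 15 lost the call, all in MLLT1 and FLT3.

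The first MV411 batch gave 204 genes at a log2 size of at least 1, 2068 relative to the median gene, 800 by limma with median-of-ratios factors and the repeated library counted once, and 743 by limma over the 7 distinct libraries. OCI-AML3 gave 389 genes at adjusted p under 0.01, 14 at a log2 size of at least 1, 318 relative to the median gene, 278 by limma with median-of-ratios factors and 441 over the 7 libraries. Leaving out each library but the lone treated MV411 one gave 218 to 655 genes in MV411, 110 to 272 in OCI-AML3 and 4 to 11 that differ between the lines. With the repeated library counted once, limma on the authors' scaling called more first-batch genes than with median-of-ratios factors, most of them lower. Cytosolic ribosomal protein genes turned from lower to higher in the first MV411 batch on the statistic relative to the median gene (adjusted p = 0.0367).

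Between the lines 130 genes differed relative to the median gene, 11 over the 7 libraries and 587 with the second MV411 batch against OCI-AML3. Between the MV411 batches 104 differed relative to the median gene and 0 by limma with the first batch taken from the 7 libraries (556 at an unadjusted p under 0.05). For the second MV411 batch against OCI-AML3, 246 genes differed with both taken relative to the median gene. Of first-batch calls 56.9% were called in the same direction in the second batch, 72.4% of those with a log2 size of at least 1 and 83.5% relative to the median gene. Count-based tests, library-size scaling, which equals TPM, and a replicate block in the tables were planned and not run.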

Other observations

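Single genes outside the leading themes also moved in the second MV411 batch, in lists that did not pass as a whole. The pro-apoptotic genes BMF (log2 fold change 0.74, SE 0.058), BIK (0.56, SE 0.054) and PMAIP1 (0.61, SE 0.080) rose together with the survival gene MCL1 (0.41, SE 0.060), while their list of 13 genes did not pass (adjusted p = 0.263 with an estimated correlation). The lactate dehydrogenase LDHA fell from 1018 ± 2.1 to 799 ± 7.0 TPM and the lactate transporter SLC16A1 from 42.8 ± 1.8 to 29.2 ± 0.72 TPM (SD, n = 4), in a glycolysis list where 8 of 25 genes rose and 11 fell. The sterol-regulated gene INSIG1 (0.42, SE 0.035) rose, and the menin gene MEN1 fell (−0.40, SE 0.030).

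Mitochondrially encoded genes, listed only in the tables, were lower in 4 of 12 relative to the median gene in the first MV411 batch, where the authors called 12 lower. In OCI-AML3 none of 12 was lower. The first-batch calls count the repeated library as a pair and were not kept with it counted once. The difference between the lines was not tested for this list.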
